A study of Mus musculus with 12 samples.

How the data were processed

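Gene expression of C2C12 mouse myoblasts was measured on 12 Illumina MouseWG-6 v2.0 R3 bead arrays, 2 for each of 6 groups: DMSO or 10 uM embelin, in growth medium or after 24 h or 48 h in differentiation medium. The labels give conflicting accounts on 2 points. For growth-medium samples, 1 field gives 0 h and another gives 24 h of treatment, so the time of exposure before harvest is uncertain for that stage. The labels also name an Agilent labelling kit, whereas the file headers and the probes are those of Illumina arrays, and the latter were followed. Replicates carry the numbers 1 and 2, without a statement that they were separate cultures, and no slide is named.

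The deposited intensity values are mean bead signals per probe from GenomeStudio, with no normalization per the file headers, and they had not been background-subtracted. The software version is 2010.2 per the labels and 1.8.0 per the file headers. The deposited detection column holds a score, 1 minus the detection p against negative-control beads, and this p was recovered by subtracting the score from 1. The deposited table also gives the standard deviation of the bead intensities and the number of beads per probe, with a median of 42 to 43 beads per array. The deposited series matrix holds log2 values. Each is the log2 signal minus the 75th percentile of the array and minus the median of the probe over the 12 arrays, since recomputing this from the signals gave 100% of the values within 0.006. Its columns have medians between -0.14 and 0.09. These values are centred on each probe and were used only as an alternative. No column belonged to a sample outside the series.

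Signals ran from 31.3 to 49278.2, and the 75th percentile of an array from 123.1 to 154.9. Between 15031 and 16314 of 45281 probes were detected at a detection p under 0.01. Symbols in the file were updated through the RefSeq gene table of the mouse assembly GRCm38.p6: 27760 probes matched a current symbol, 7994 matched a synonym and 9527 kept the name in the file. Of the genes tested, 7774, 1912 and 1766 carry names of these kinds.

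Signals were background-corrected, quantile normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3 (offset 16), with the negative-control distribution inferred from the detection p. Probes detected at p under 0.01 on both arrays of at least 1 group were kept (16981 probes). For each gene the probe with the highest mean was used, giving 11452 genes. Among 3829 genes with several probes, 19 had probes called in opposite directions for embelin at 48 h and 71 for DMSO cells at 48 h. Of the genes named in the text, H2ac20 is among them in both comparisons. The 6 group means were fitted with limma on all 12 arrays (6 residual degrees of freedom, 4.51 prior degrees of freedom). The contrasts were embelin against DMSO at each stage, each time in differentiation medium against growth medium within each treatment, the interactions at 24 h and 48 h, and the mean embelin effect. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

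Where a gene was detected on no array of a group, only a lower bound of its fold change is given, written as at least N-fold. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest detected signal on the array and the probe's own signal. For 27 gene lists, 22 of pathways and 5 of cell types, fixed before the data were examined, called genes were counted. Their shift was tested with camera (preset inter-gene correlation 0.01), with camera using an estimated correlation, and with fry. List p-values were adjusted over the 27 lists within a comparison. Where the text gives a count adjusted over the list alone, the gene p-values were adjusted within that list.

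The text names genes by a fixed rule. It names the 10 largest changes each way among called genes with both arrays of a group above both arrays of the other, and the 5 largest each way for the interactions. It names Kat2b, Kat2a, Ep300, Crebbp, Myod1, Myog, Mef2c, Cdkn1a and Hmox1 in each comparison, Xiap once since it was not detected, and up to 4 members of each list described. Predicted and accession-only symbols were skipped. The share of the differentiation response seen in embelin cells was the slope through the origin of embelin on DMSO log2 changes between growth medium and 48 h, over genes changed by at least 1 in the DMSO cells of a replicate number and measured in the other number.

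Replicate numbers were not used as pairs in the fit. The pipeline was tested on simulated data in which 67, 67 and 66 of 11452 genes were changed by 0.5, 1 and 2 log2 units in a single group. It recovered 16, 62 and 66 of these at 48 h with 7 false calls among 151, 21, 66 and 65 at 24 h with 2 among 154, and 29, 63 and 66 in growth medium with 23 among 181. In this setting, changes of 0.5 were often missed with 2 arrays per group. Far fewer genes were changed there than the 4544 called for embelin at 48 h. The adjusted threshold is stricter when few genes change, so these rates do not carry over to that comparison. Alternatives tried were no background correction, another background model, scaling by the median or the 75th percentile, an offset of 50, the series matrix, other detection filters, every probe, the replicate block, a trended and robust prior, array weights, the compared arrays alone, stricter thresholds and leaving out each array. Where an array is left out, the lone array of its group is assumed to vary like those of the other groups. The standard deviation of the beads was not used here.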

Results

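Gene expression was measured on 12 Illumina mouse whole-genome bead arrays in C2C12 cells, an established mouse myoblast line that leaves the cell cycle and fuses into myotubes when serum is lowered. Cells had received either the solvent DMSO or 10 uM embelin, a plant benzoquinone that the series title describes as an inhibitor of the acetyltransferase PCAF (gene Kat2b) and that is also known as an inhibitor of XIAP. The 3 stages were growth medium with 20% fetal bovine serum, 24 h in differentiation medium with 2% horse serum, and 48 h in differentiation medium. Each of the 6 groups held 2 arrays. Every comparison between groups rests on n = 2 arrays per group, and the number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Between 15031 and 16314 of the 45281 probes were detected per array, and 11452 genes were tested. Fold changes are log2 differences of normalized signal with their standard error (SE), and adjusted p-values come from limma unless a list test is named.

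Arrays separated first by medium and then, at 48 h, by treatment. The leading principal component held 70.9% of the variance and ran from growth medium through 24 h (18.6 to 28.5) to 48 h in differentiation medium (39.3 to 42.9). The component after it held 12.5% and parted the DMSO arrays at 48 h (-17.9 and -27.2) from the embelin arrays at 48 h (35.4 and 41.9). A single array stood apart from its group: replicate 2 of embelin in growth medium lay at -48.7 on the leading component, while the other 3 growth-medium arrays lay between -70.7 and -70.2. The spread between the arrays of that group (root mean square SD 0.235 log2 units) was the largest of the 6 groups, the others lying between 0.135 and 0.176.

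**Figure D1:**
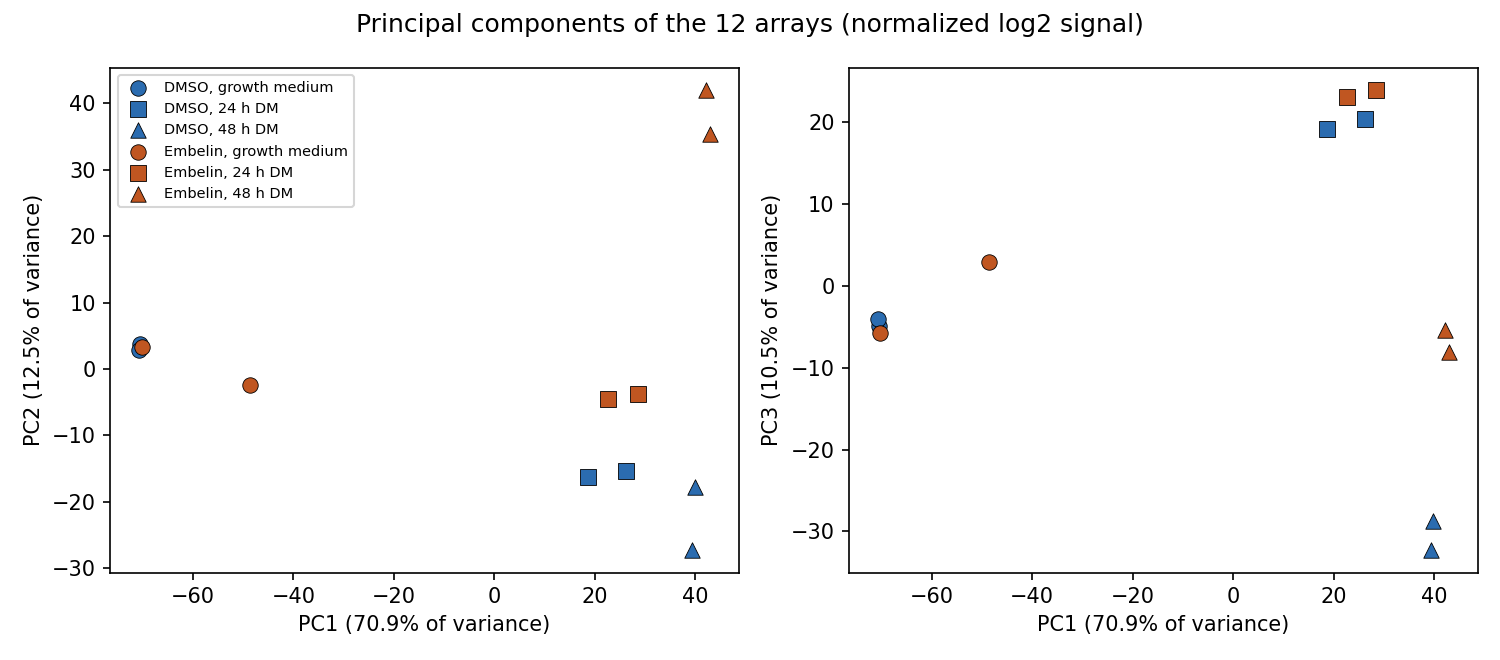
Principal components of the normalized log2 signal of 12 arrays, each point an array, colour for treatment and shape for stage; the left panel sets component 1 (70.9% of variance) against component 2 (12.5%) and the right panel against component 3 (10.5%). Embelin and DMSO arrays lie farthest apart at 48 h, and replicate 2 of embelin in growth medium lies at -48.7 on component 1, away from the other growth-medium arrays.

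Differentiation without the inhibitor was measured in the DMSO cells, as the background for every embelin result. After 48 h in differentiation medium, genes of the contractile apparatus rose far above their level in growth medium. Actn2 (sarcomeric alpha-actinin) rose at least 268-fold, Myh8 (perinatal myosin heavy chain) at least 150-fold and Ckm (muscle creatine kinase) at least 89.0-fold, each against a growth-medium signal not above background. The cell cycle inhibitor Cdkn1c rose by 8.46 log2 units (SE 0.95, adjusted p = 2.09e-05), Cox8b by 6.50 (SE 0.43), the calcium-binding protein gene Hrc by 6.19 (SE 0.37) and the muscle phosphoglycerate mutase gene Pgam2 by 6.03 (SE 0.38). Asb2, Tceal5 and Dhrs7c rose at least 74.6-fold, 71.1-fold and 53.4-fold. In the other direction, the proliferin genes Prl2c3 and Prl2c2 fell at least 96.7-fold and by 6.71 log2 units (SE 0.84), Prl2c2 being detected on 1 of the 2 DMSO arrays at 48 h. The glutathione transferase genes Gsta1 and Gsta2 fell at least 56.8-fold and 41.3-fold, and Gsta4 fell by 4.71 log2 units (SE 0.26). Genes of the Prl2c and Gsta families are near-identical to each other, so a probe may read several of them. Avil fell at least 40.7-fold and Prr9 at least 13.4-fold. The growth factor gene Areg fell by 5.42 log2 units (SE 0.42), Cdsn fell by 4.63 (SE 0.43) and the BMP antagonist gene Grem1 fell by 4.47 (SE 0.36). The highest adjusted p among these 20 genes was 4.63e-05, that of Prl2c2.

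Of the genes fixed for every comparison, Myog rose by 4.75 log2 units at 48 h (adjusted p = 8.02e-06), Mef2c by 4.71 (adjusted p = 4.68e-08), Myod1 by 1.99 (adjusted p = 2.34e-06) and Cdkn1a by 1.73 (adjusted p = 4.78e-07) in the DMSO cells. Kat2b, which encodes PCAF, rose by 0.59 (adjusted p = 0.00344) and was detected on 1 of the 2 DMSO arrays in growth medium. Kat2a, its paralog, fell by 0.88 (adjusted p = 0.000112), and Hmox1 (heme oxygenase) fell by 3.60 (adjusted p = 7.72e-08). Ep300 fell by 0.47 (adjusted p = 0.00798), a call lost without replicate 1 of DMSO in growth medium (adjusted p = 0.0644) or at 48 h (adjusted p = 0.0763). Crebbp did not pass the test (log2 fold change -0.04, adjusted p = 0.972). None of the 4 Xiap probes was detected on any array.

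All 31 measured sarcomere genes rose at 48 h in DMSO cells, with a median of 4.81 log2 units (camera adjusted p = 3.87e-18, adjusted p = 0.256 with an estimated correlation). With an estimated correlation, camera called 0 of the 27 lists in every comparison, so failing that test says little about a list. The list of excitation, neuromuscular and muscle metabolic genes had 27 of 27 higher, among them Casq2 at 5.98 and Atp2a1, the fast-muscle calcium pump gene, at 5.84 (camera adjusted p = 9.54e-16, adjusted p = 0.225 with an estimated correlation). Among the myogenic regulatory factors 8 of 10 rose (camera adjusted p = 8.23e-05, adjusted p = 0.225 with an estimated correlation). Of 15 fusion genes 8 rose, led by Mymk (myomaker) at 5.18, and 3 fell (camera adjusted p = 0.00884, adjusted p = 0.317 with an estimated correlation). Extracellular matrix genes were higher in 18 and lower in 2 of 22, with Col6a1 at 4.51 and Col1a1 at 4.03 (camera adjusted p = 2.82e-06, adjusted p = 0.317 with an estimated correlation). All 15 interferon response genes rose, Oasl2 at least 17.3-fold and Igtp at least 14.4-fold (camera adjusted p = 8.27e-08, adjusted p = 0.225 with an estimated correlation). Sterol synthesis genes rose in 18 of 22, with Dhcr7 at 2.17 (camera adjusted p = 9.57e-06, adjusted p = 0.317 with an estimated correlation). Glycolysis and hypoxia genes rose in 16 of 23 (camera adjusted p = 5.23e-05, adjusted p = 0.339 with an estimated correlation). The insulin-like growth factor list had 10 higher and 4 lower of 15, with Igf2 at 4.15 and H19 at 2.72 (camera adjusted p = 0.0134, adjusted p = 0.435 with an estimated correlation), a call lost with genes detected on all arrays (adjusted p = 0.0749).

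Proliferation genes moved the other way in the DMSO cells at 48 h. All 30 DNA replication genes fell, with Chaf1b at -3.25 and Mcm10 at -3.04 (median -2.21, camera adjusted p = 4.24e-14, adjusted p = 0.225 with an estimated correlation). Of 21 G2/M genes 20 fell, with Aurkb at -2.08 and Foxm1 at -2.05 (median -1.54, camera adjusted p = 4.81e-08, adjusted p = 0.317 with an estimated correlation). All 22 NRF2 and redox genes fell, including Nqo1 at -4.37 and Gclm at -4.30 (camera adjusted p = 9.2e-10, adjusted p = 0.225 with an estimated correlation). All 5 aryl hydrocarbon receptor targets fell (camera adjusted p = 0.0105, adjusted p = 0.317 with an estimated correlation). The integrated stress response list had 15 lower and 4 higher of 24, the latter led by Fgf21 at 5.91 (camera adjusted p = 0.039, adjusted p = 0.388 with an estimated correlation). That call was lost without replicate 1 of DMSO in growth medium (adjusted p = 0.0651), without replicate 1 of DMSO at 48 h (adjusted p = 0.0514) or without either embelin array in growth medium (adjusted p = 0.0548). Of 28 mitochondrial genes 8 rose and 1 fell (median 0.18, camera adjusted p = 0.0333, adjusted p = 0.317 with an estimated correlation), but the median turned to -0.11 under median scaling and the call was lost there (adjusted p = 0.513), under 75th percentile scaling (adjusted p = 0.161) and with the series matrix (adjusted p = 0.244). It was lost too without replicate 1 of DMSO in growth medium (adjusted p = 0.0555) and without replicate 2 of DMSO at 48 h (adjusted p = 0.0789), where 4 genes rose, against 5 without replicate 1 of DMSO at 48 h. Over the lists alone the counts were the same, except 19 of 22 matrix genes higher, 2 sterol genes lower and 5 mitochondrial genes higher with 0 lower, adjusted over the list alone. With genes not above background in a group set at their bound, the median was 1.38 instead of 1.86 for the myogenic factors, 2.61 instead of 2.88 for the excitation list and 1.37 instead of 1.53 for the interferon list.

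Over all genes tested, 7103 differed between 48 h and growth medium in DMSO cells, 3140 higher and 3963 lower, and 2548 by at least 1 log2 unit. Scaling by the array median gave 2103 higher and 5425 lower, and moved the median of all genes to -0.33. At 24 h, 6600 genes differed (2989 higher and 3611 lower; 1951 and 5099 under median scaling). Myog was already up by 4.56 at 24 h (adjusted p = 1.56e-05), Mef2c by 2.79, Myod1 by 2.01, Kat2b by 0.90 and Cdkn1a by 0.83. Kat2a fell by 0.59 and Hmox1 by 3.48 at 24 h, while Ep300 (-0.06, adjusted p = 0.729) and Crebbp (-0.22, adjusted p = 0.842) did not pass. At 24 h 30 of 31 sarcomere genes (camera adjusted p = 1.02e-14, adjusted p = 0.247 with an estimated correlation) and 24 of 27 excitation and metabolic genes (camera adjusted p = 3.14e-11, adjusted p = 0.247 with an estimated correlation) had risen. All 30 replication genes (camera adjusted p = 1.47e-12, adjusted p = 0.247 with an estimated correlation) and 19 of 21 G2/M genes (camera adjusted p = 1.21e-05, adjusted p = 0.3 with an estimated correlation) had fallen. Camera called 14 of the 27 lists at 24 h, and with an estimated correlation 0, their lowest adjusted p being 0.247.

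The question of the series is how gene expression in differentiating cells changes when PCAF is inhibited by embelin, and 48 h in differentiation medium gave by far the largest response. Most called members of the inflammatory and hypoxia lists were higher with embelin than with DMSO, and the G2/M genes, 10 of 13 measured histone H2A genes and the called sarcomere genes were lower. Among the 10 largest increases were the acute-phase genes Saa3 (log2 fold change 4.25, SE 0.97) and Cp (3.56, SE 0.37), the lipoprotein lipase inhibitor gene Angptl4 (3.97, SE 0.70), the carbonic anhydrase gene Car12 (3.34, SE 0.39), the collagenase gene Mmp13 (3.33, SE 0.37), the aldehyde dehydrogenase gene Aldh3a1 (3.31, SE 0.21) and the chemokine genes Cxcl12 (3.24, SE 0.41) and Cxcl1 (3.18, SE 0.38). Rasl11a was higher by 3.21 (SE 0.28), and Prl2c3, not above background in DMSO cells at 48 h, was at least 7.77-fold higher. Rasl11a and Mmp13 were detected on 1 of the 2 DMSO arrays. The DMSO arrays at 48 h differed widely for Saa3 (log2 signals 10.478 and 6.072) and for Angptl4 (9.842 and 6.673). The 10 largest decreases held Parm1 (-4.00, SE 0.65), the H2A genes H2ac23 (-3.30, SE 0.11), H2ac12 (-3.26, SE 0.27), H2ac15 (-3.24, SE 0.18) and H2ac22 (-3.14, SE 0.20), the collagen gene Col8a2 (-3.24, SE 0.37), Cdkn1c (-3.24, SE 0.95), the laminin gene Lama1 (-3.13, SE 0.27), Tceal6 (at least 6.38-fold lower) and the mitotic survivin gene Birc5 (-3.10, SE 0.23). H2A genes are near-identical in sequence, so their probes are uncertain as measures of single genes. Col8a2 and Lama1 were detected on 1 of the 2 embelin arrays. Adjusted p-values of these 20 genes lay between 1.16e-07 and 0.0203.

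The acetyltransferase named as the target was itself higher with embelin at 48 h, Kat2b by 0.51 (SE 0.14, adjusted p = 0.0138) and Ep300 by 0.58 (adjusted p = 0.00467). Kat2a (-0.13, adjusted p = 0.448) and Crebbp (0.32, adjusted p = 0.792) did not pass. Myod1 was lower by 0.59 (log2 fold change -0.59, adjusted p = 0.0171) and Mef2c by 1.26 (-1.26, adjusted p = 0.000928), whereas Myog, the myogenic factor that rises with commitment, stood at -0.02 (adjusted p = 0.978). In a limma fit of every probe, Mef2c probes at -1.15 (adjusted p = 0.112) and -0.58 (adjusted p = 0.0533) did not pass, and another at -1.09 did (adjusted p = 0.00478). Cdkn1a was higher by 0.40 (adjusted p = 0.02) and Hmox1 by 1.44 (adjusted p = 0.000127). In the limma fit of every probe, other Cdkn1a probes passed at 0.56 (adjusted p = 0.0285) and 0.60 (adjusted p = 0.00748). Another Kat2b probe passed there at 0.56 (adjusted p = 0.0134). These probes were read on the same arrays. Leaving out replicate 2 of embelin at 48 h ended the calls of Kat2b (adjusted p = 0.102), Ep300 (adjusted p = 0.0518), Myod1 (adjusted p = 0.149), Cdkn1a (adjusted p = 0.103), Cdkn1c (adjusted p = 0.132) and Ckm (adjusted p = 0.0564). Kat2b was also lost without replicate 1 of DMSO at 48 h (adjusted p = 0.09), and Myod1, Cdkn1a and Cdkn1c were lost without either DMSO array at 48 h (adjusted p from 0.0543 to 0.0844). Cdkn1a was lost too without replicate 1 of embelin (adjusted p = 0.0557) and under scaling by the median (adjusted p = 0.0899) or the 75th percentile (adjusted p = 0.244), and Myod1 under median scaling (adjusted p = 0.0512). With the series matrix Kat2b stood at 0.295 and lost its call (adjusted p = 0.0538), as did Cdkn1a (adjusted p = 0.127), whose value of 0.40 became 0.21 under 75th percentile scaling. Cdkn1c lost its call without a detection filter (adjusted p = 0.073) and with a trended and robust prior (adjusted p = 0.0818).

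**Figure D2:**
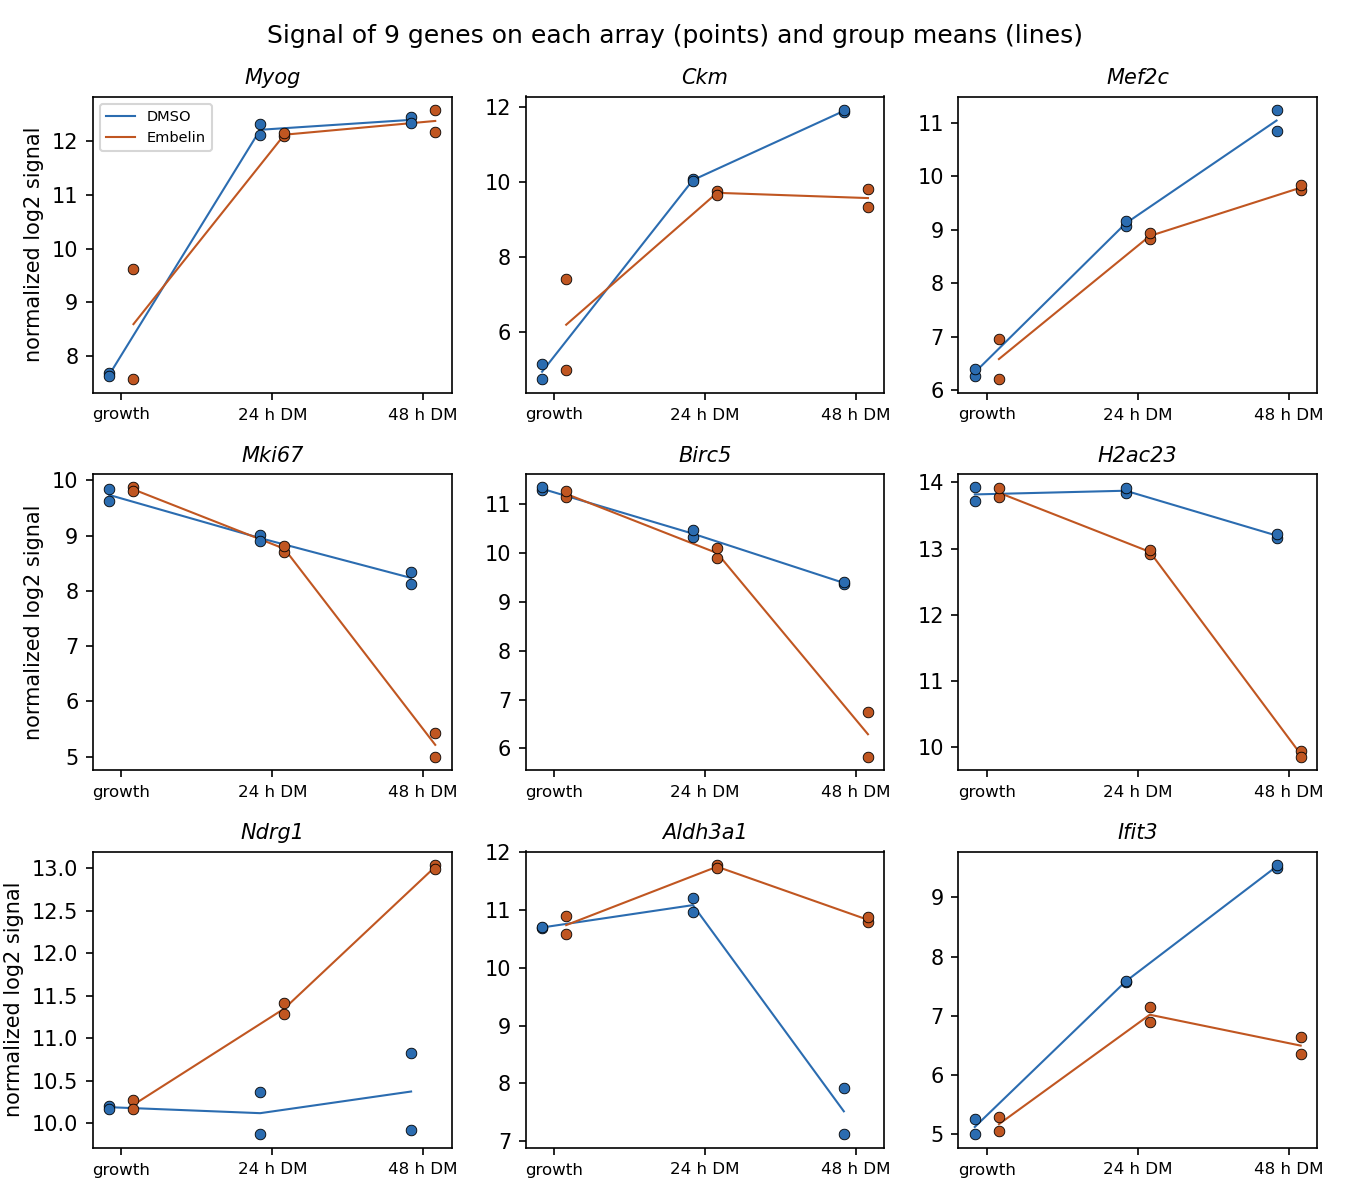
Normalized log2 signal (y axis) of 9 genes at the 3 stages (x axis), with points for the 2 arrays of each group and lines through the group means, blue for DMSO and orange for embelin. Myog reached the same range in both treatments, Ckm, Mef2c, Mki67, Birc5, H2ac23 and Ifit3 were lower with embelin at 48 h, and Ndrg1 and Aldh3a1 were higher.

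Muscle and cell cycle lists were lower with embelin at 48 h. All 21 measured G2/M genes were lower than in DMSO cells, with Mki67 at -3.02, Plk1 at -2.81 and Aurkb at -2.81 (median -2.44, camera adjusted p = 2.97e-19, adjusted p = 0.152 with an estimated correlation). Mki67 and Aurkb were detected on 1 of the 2 embelin arrays. Of 30 replication genes 20 were lower and 1 higher, with Mcm5 at -2.77 and Tk1 at -2.60 (camera adjusted p = 8.49e-09, adjusted p = 0.277 with an estimated correlation), and the median was -0.94, or -0.72 with 5 genes at their bound. Sarcomere genes were lower in 16 of 31 and higher in 0, with Mybpc1 at -2.17, Actn2 at -2.13 and Myh1 at -2.07 (median -0.78, camera adjusted p = 3.14e-06, adjusted p = 0.382 with an estimated correlation). Among the excitation and metabolic genes 19 of 27 were lower, including Ckmt2 at least 4.55-fold, Ampd1 at least 4.16-fold, Pgam2 at -2.44 and Ckm at -2.32 (median -0.81, camera adjusted p = 2.58e-08, adjusted p = 0.309 with an estimated correlation). Myogenic factors were lower in 5 of 10, including Myf6 at least 1.78-fold, Smyd1 at -1.09 and Tead4 at -0.87 (median -0.34, camera adjusted p = 0.0331, adjusted p = 0.317 with an estimated correlation). That list call was lost without replicate 2 of DMSO (adjusted p = 0.0983) or of embelin (adjusted p = 0.0542) at 48 h, and with genes detected on all arrays (adjusted p = 0.149). Of 28 mitochondrial genes 24 were lower, with Ppargc1a at least 2.59-fold, Idh3a at -1.43 and Cycs at -1.22 (median -0.54, camera adjusted p = 3.79e-09, adjusted p = 0.119 with an estimated correlation). Interferon response genes were lower in 14 and higher in 1 of 15, with Ifit3 at -3.02, Usp18 at least 4.87-fold lower and Oasl2 at -2.46 (median -1.15, camera adjusted p = 7.97e-08, adjusted p = 0.152 with an estimated correlation). Sterol synthesis genes were lower in 8 and higher in 1 of 22, with Mvd at -1.50 and Dhcr7 at -1.21 (median -0.38, camera adjusted p = 0.00347, adjusted p = 0.382 with an estimated correlation). Adjusted over the list alone, the numbers lower were 21 for replication, 17 for sarcomere, 22 for excitation, 25 for mitochondria and 10 for sterol synthesis with 2 higher; the others were the same. Without replicate 2 of embelin at 48 h, 10 sarcomere and 12 excitation genes were lower, and without replicate 2 of DMSO at 48 h 12 excitation genes were. Without either embelin array in growth medium, which enters this comparison only through the pooled spread, 25 sarcomere genes were lower.

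Of the lists that were higher with embelin at 48 h, glycolysis and hypoxia had the lowest camera adjusted p, though not the highest median. It had 22 of 23 genes higher and 0 lower, including Ndrg1 at 2.65, the glucose transporter genes Slc2a3 at 2.44 and Slc2a1 at 1.70, and the oxygen sensor gene Egln1 at 1.96 (median 0.95, camera adjusted p = 3.72e-10, adjusted p = 0.214 with an estimated correlation). All 5 aryl hydrocarbon receptor targets were higher, with Aldh3a1, Ugt1a6a at 2.13 and Cyp1b1 at 1.74 (median 1.74, camera adjusted p = 0.000339, adjusted p = 0.214 with an estimated correlation). NF-kB targets and inflammatory genes were higher in 10 and lower in 2 of 17, with Saa3, Cxcl12, Cxcl1 and Nfkbiz at 1.81 (camera adjusted p = 0.000339, adjusted p = 0.274 with an estimated correlation). Of 18 p53 targets and cell cycle exit genes 10 were higher, with Trp53inp1 at 1.38, Mdm2 at 1.30 and Ccng1 at 1.24, and 1, Cdkn1c, was lower (camera adjusted p = 0.00252, adjusted p = 0.152 with an estimated correlation). NRF2 and redox genes were higher in 10 and lower in 2 of 22, with Epha2 at 1.44, Hmox1 and Gstm1 at 1.28 (camera adjusted p = 0.00985, adjusted p = 0.382 with an estimated correlation). Matrix genes were higher in 10 and lower in 2 of 22, with the cross-linking enzyme gene Lox at 1.85, Fn1 at 1.72 and Ccn1 at 1.67 (camera adjusted p = 0.0138, adjusted p = 0.518 with an estimated correlation). Of the markers of quiescent or reserve cells, only Cxcr4, Foxo3, Sdc3 and Sdc4 were measured. The listed Pax7, Pax3, Cd34, Spry1, Calcr, Chodl and Rbl2 were not among the genes tested. All 4 measured markers were higher, with Cxcr4 at 1.02 and Foxo3 at 0.94 (camera adjusted p = 0.00252, adjusted p = 0.152 with an estimated correlation). Adjusted over the list alone, these counts were the same. Leaving out replicate 2 of embelin at 48 h gave 6 matrix genes higher and 1 lower, and leaving out replicate 2 of embelin in growth medium gave 3 lower p53 list genes instead of 1.

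The remaining lists were not called by camera at 48 h. Members went both ways among apoptosis regulators (8 higher and 2 lower of 18, camera adjusted p = 0.18), with Pmaip1, a death-promoting gene detected on 1 of the 2 embelin arrays, at -2.01, Bid at -1.22 and the survival gene Bcl2l1 at 1.16. The integrated stress response had 5 higher and 10 lower of 24 (camera adjusted p = 0.384), with Gpt2 at -1.19, Phgdh at -1.05, Vldlr at 1.12 and Ddit3 at 1.02. ER unfolded protein response genes were higher in 5 of 17, with Hsp90b1 at 0.76 (camera adjusted p = 0.22). Heat shock genes were higher in 3 and lower in 5 of 13, with Hspb1 at -1.07 and Hspb2 at -0.71 (camera adjusted p = 0.314). Acetyltransferases, deacetylases and coactivators were higher in 7 and lower in 5 of 24, with Hdac11 at -1.28, Kat6b at 0.72, Sirt2 at -0.64 and Kat5 at 0.60 (camera adjusted p = 0.509). In a limma fit of every probe, another probe of Kat6b (0.34, adjusted p = 0.156) and of Kat5 (0.42, adjusted p = 0.203) did not pass. Inhibitors of myogenesis were higher in 4 and lower in 5 of 16, with Heyl at least 3.48-fold lower, Hey1 at -2.10, Twist2 at 1.11 and Id2, detected on 1 of the 2 DMSO arrays, at 1.61 (camera adjusted p = 0.517). Fusion genes were higher in 5 and lower in 4 of 15, with Adam12 at -1.56 and Dysf at -0.85 (camera adjusted p = 0.849), and their median of 0.18 and mean of -0.01 differed in sign. The growth factor axis had 5 higher and 4 lower of 15, with Igfbp3, detected on 1 of the 2 embelin arrays, at -2.86, Igfbp2 at 1.64 and Irs2 at 1.09; its median (-0.03) and mean (-0.06) were negative while camera gave the direction as up (adjusted p = 0.814). Of other cell types, adipocyte markers had 1 higher and 1 lower of 3 (camera adjusted p = 0.933), osteoblast and chondrocyte markers 1 higher of 3 (camera adjusted p = 0.18), smooth muscle markers 3 lower of 6 (camera adjusted p = 0.114) and fibro-adipogenic markers 2 higher and 1 lower of 6 (camera adjusted p = 0.283). Adjusted over the list alone, 9 apoptosis regulators and 4 fibro-adipogenic markers were higher. With replicate 2 of embelin at 48 h left out, the numbers higher and lower were 4 and 5 for the integrated stress response, 2 and 0 for the ER response, 1 and 2 for heat shock, 3 and 2 for acetyltransferases, 2 and 3 for inhibitors of myogenesis and 3 and 2 for fusion, and leaving out other arrays of 48 h lowered several of them too.

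At 48 h 4544 genes differed between embelin and DMSO, 2264 higher and 2280 lower, and 1005 of them by at least 1 log2 unit (455 higher and 550 lower). Median scaling gave 2379 higher and 1461 lower. Without replicate 2 of embelin at 48 h the count was 2939.

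**Figure D3:**
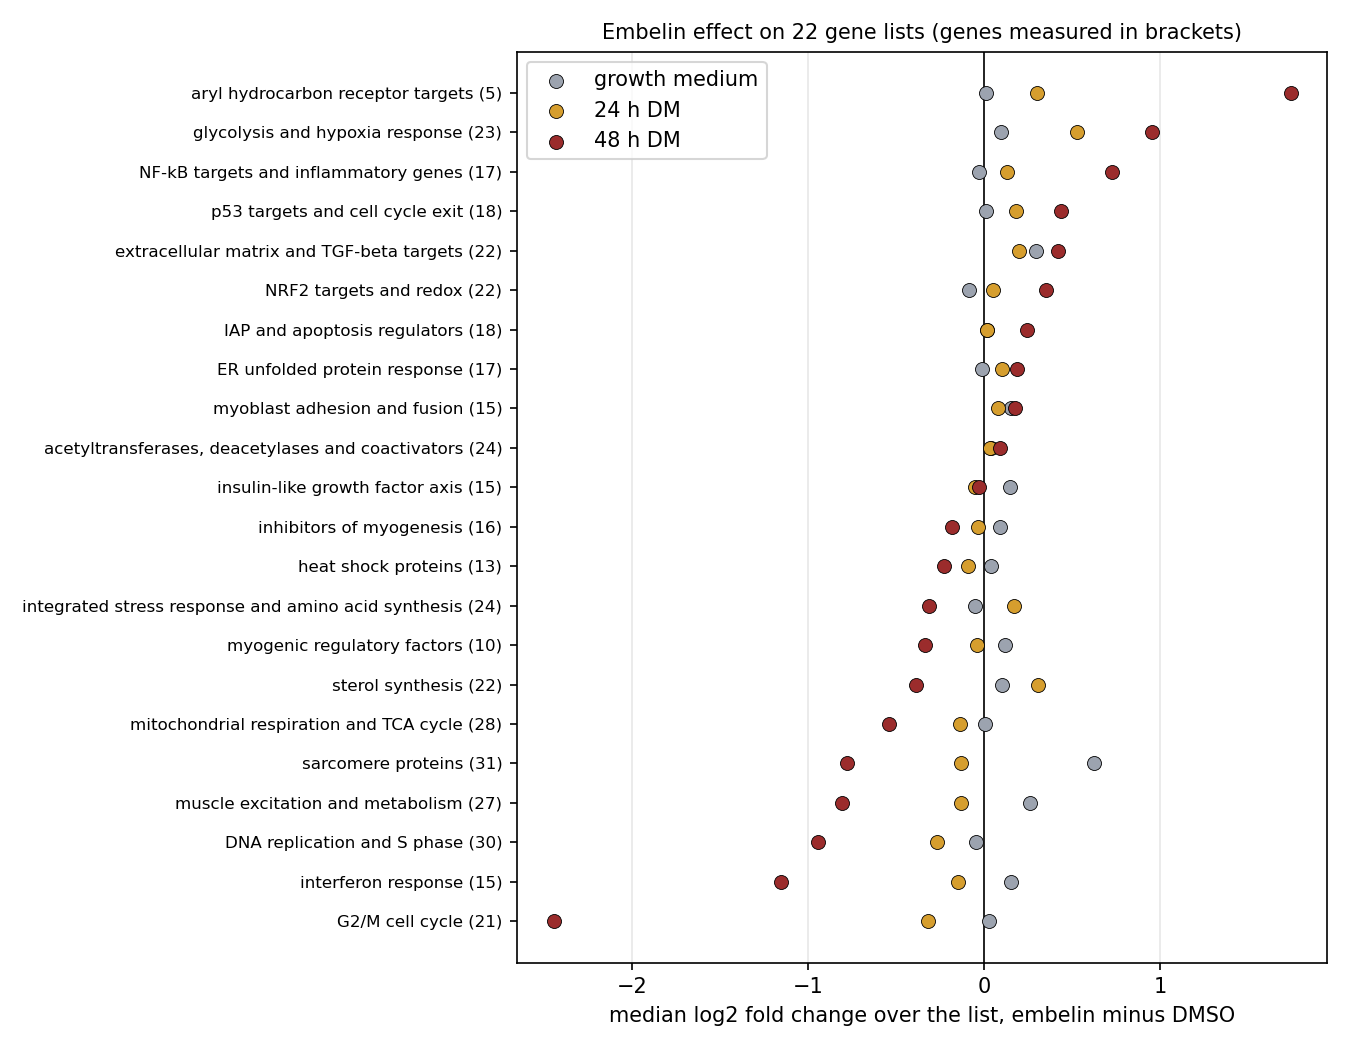
Median log2 fold change of embelin against DMSO (x axis) over each of 22 gene lists (y axis, number of measured genes in brackets), grey for growth medium, yellow for 24 h and red for 48 h in differentiation medium. At 48 h the medians run from -2.44 for G2/M genes to 1.74 for aryl hydrocarbon receptor targets; the sarcomere median of 0.63 in growth medium fell to 0.08 without replicate 2 of embelin, and the growth-medium medians of the glycolysis and insulin-like growth factor lists turned negative without it.

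At 24 h in differentiation medium the effect of embelin was small, and 4 of the 6 genes called were histone H2A genes. H2ac23 was lower by 0.92 (log2 fold change -0.92, SE 0.11, adjusted p = 0.0322), H2ac20 by 0.90 (-0.90, SE 0.12, adjusted p = 0.0322), H2ac10 by 0.82 (-0.82, SE 0.10, adjusted p = 0.0322) and H2ac13 by 0.72 (-0.72, SE 0.10, adjusted p = 0.0478). The sterol synthesis gene Hsd17b7 was higher by 0.71 (SE 0.09, adjusted p = 0.0322) and the TNF family ligand gene Tnfsf9 by 0.85 (SE 0.12, adjusted p = 0.0478). Another probe of H2ac20 stood at 0.38 at 24 h (adjusted p = 0.408) and was higher by 1.79 at 48 h, where the probe used was lower (-1.65), so the direction of H2ac20 is uncertain. These 6 genes were all that passed limma at an adjusted p under 0.05, while 1266 genes had an unadjusted p under 0.05. With the replicate number as a block in the fit, 0 genes passed. Of the 6, 5 were called in the same direction at 48 h. The count is fragile: it was 0 under median or 75th percentile scaling, 51 without background correction, 39 with a trended and robust prior, and between 0 and 9 with an array left out. The balance of directions turned as well, with 29 higher and 22 lower without background correction and 28 higher and 11 lower with the trended and robust prior. It was 0 without replicate 1 or 2 of embelin at 24 h (H2ac23, adjusted p = 0.218 and 0.241). None of the genes fixed for every comparison passed at 24 h: Kat2b stood at 0.35 (adjusted p = 0.372), Kat2a at -0.28 (adjusted p = 0.436), Ep300 at 0.06, Crebbp at 0.13, Myod1 at 0.00 (adjusted p = 0.999), Myog at -0.09 (adjusted p = 0.963), Mef2c at -0.24 (adjusted p = 0.728), Cdkn1a at 0.19 (adjusted p = 0.604) and Hmox1 at 0.33 (adjusted p = 0.529).

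Glycolysis and hypoxia genes were shifted together at 24 h, all 23 having a positive log2 fold change with a median of 0.53 (camera adjusted p = 2.76e-19, adjusted p = 0.143 with an estimated correlation). None was called over all genes, and 18 were higher when adjusted over the list alone, Egln1 standing at 0.96 (adjusted p = 0.103) and Slc2a1 at 0.65 (adjusted p = 0.132). The sterol synthesis list had 1 gene called, Hsd17b7, and 7 higher adjusted over the list alone (median 0.31, camera adjusted p = 4.03e-10, adjusted p = 0.206 with an estimated correlation). No member was called over all genes in the lists that follow. G2/M genes had a median of -0.32 (camera adjusted p = 4.18e-08, adjusted p = 0.321 with an estimated correlation), with 1 lower adjusted over the list alone. Replication genes had a median of -0.27 (camera adjusted p = 6.03e-08, adjusted p = 0.321 with an estimated correlation), with 4 lower adjusted over the list alone. Medians were 0.18 for p53 targets (camera adjusted p = 4.18e-05, adjusted p = 0.132 with an estimated correlation), 0.17 for the integrated stress response (camera adjusted p = 4.9e-05, adjusted p = 0.223 with an estimated correlation) and 0.20 for matrix genes (camera adjusted p = 3.81e-05, adjusted p = 0.353 with an estimated correlation). Adjusted over the list alone, 3, 3 and 2 of their members were higher. The 4 measured quiescent or reserve cell markers, which leave out Pax7 and Cd34, had a median of 0.42 (camera adjusted p = 0.000263, adjusted p = 0.132 with an estimated correlation). All 4 were higher adjusted over the list alone. Mitochondrial genes had a median of -0.13 (camera adjusted p = 6.6e-05, adjusted p = 0.156 with an estimated correlation).

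The last 4 lists called by camera at 24 h were sarcomere genes (median -0.13, adjusted p = 0.0177), excitation and metabolic genes (-0.13, adjusted p = 0.0107), aryl hydrocarbon receptor targets (0.30, adjusted p = 0.0248) and interferon response genes (-0.15, adjusted p = 0.048). Their adjusted p with an estimated correlation was 0.673, 0.599, 0.353 and 0.456. Each call was lost without replicate 1 of DMSO at 24 h (adjusted p = 0.26, 0.171, 0.384 and 0.291) and without replicate 2 of embelin at 24 h (adjusted p = 0.142, 0.0855, 0.133 and 0.262). None of the genes in these lists was called over all genes, and adjusted over the list alone 2 interferon genes were lower.

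In growth medium no gene passed limma at an adjusted p under 0.05 between embelin and DMSO, and 674 genes had an unadjusted p under 0.05. Myog stood at 0.94 with an adjusted p of 0.861, because its 2 embelin arrays differed widely (SD 1.46). From replicate 2 of embelin alone, Myog was called at 1.97 (adjusted p = 0.000144) among 338 genes, and without that replicate 2 genes were called, the mitochondrially encoded MT-ND5 at -1.77 and the protease gene Prss23 at -1.28, both at adjusted p = 0.0411. The last pair was named after its values were seen. Kat2b, Kat2a, Ep300, Crebbp, Myod1, Mef2c, Cdkn1a and Hmox1 did not pass with both arrays (adjusted p from 0.861 to 0.998). With both arrays, camera called 12 of the 27 lists: sarcomere genes had a median of 0.63 (camera adjusted p = 1.17e-14, adjusted p = 0.515 with an estimated correlation) and matrix genes of 0.29, or 0.26 with genes at their bound (camera adjusted p = 1.08e-06, adjusted p = 0.515 with an estimated correlation). Without replicate 2 of embelin in growth medium, the medians were 0.08 and 0.06, and camera called 0 of the 27 lists. With an estimated correlation 0 lists were called either way.

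In embelin-treated cells, 7226 genes differed between 48 h and growth medium (3479 higher and 3747 lower; 2550 and 4506 under median scaling) and 6552 at 24 h (3127 and 3425; 2120 and 4567 under median scaling). Each of these comparisons includes replicate 2 of embelin in growth medium, which stood toward the differentiated arrays. The muscle programme rose here too: 30 of 31 sarcomere genes were higher at 48 h (median 3.18, camera adjusted p = 1.02e-12, adjusted p = 0.251 with an estimated correlation), and Myog had risen by 3.53 at 24 h and 3.79 at 48 h. Mef2c rose by 2.30 and 3.21, Myod1 by 1.65 and 1.04, Kat2b by 1.02 and 0.86 and Cdkn1a by 0.85 and 1.95 at the same times. Kat2a fell by 0.86 and fell by 0.99, and Hmox1 fell by 2.99 and fell by 2.00. Ep300 and Crebbp passed at neither time. All 21 G2/M genes (median -4.00, camera adjusted p = 6.84e-15, adjusted p = 0.245 with an estimated correlation) and all 30 replication genes (median -3.12, camera adjusted p = 4.78e-17, adjusted p = 0.245 with an estimated correlation) were lower at 48 h than in growth medium. All 23 glycolysis and hypoxia genes were higher (median 1.81, or 1.60 with 1 gene at its bound, camera adjusted p = 7.72e-11, adjusted p = 0.245 with an estimated correlation). The counts were the same adjusted over the list alone. Over genes chosen on the other replicate number, the change from growth medium to 48 h in embelin cells was 0.639 and 0.866 of that in DMSO cells (slope through the origin, for numbers 2 and 1). Genes that rose in DMSO cells gave 0.512 and 0.789, and genes that fell gave 0.923 and 1.03. With the mean of the DMSO growth-medium arrays as the baseline, chosen after seeing the data, the slopes were 0.825 and 0.879. Under that baseline, genes that rose gave 0.741 and 0.804, and genes that fell gave 1.01 and 1.04. The value of 0.512 thus depends on the embelin array that stood apart.

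The difference between the embelin effects in differentiation and growth medium was tested as an interaction. The labels give 48 h of treatment for the 48 h samples, and 24 h or 0 h for the growth-medium samples. At 48 h, medium and length of exposure to embelin therefore cannot be told apart. Exposure is equal only in the comparison at 24 h, if the field with 24 h holds for growth medium. Hypoxia genes were among those raised more by embelin at 48 h in differentiation medium than in growth medium. Mitotic, sarcomere and interferon genes were among those lowered more. At 48 h 2736 genes differed in this way, 1301 upward and 1435 downward. The 5 genes named by the fixed rule upward were Saa3 (4.28, adjusted p = 0.045), Angptl4 (adjusted p = 0.0149), Car12 (3.46), Cxcl12 (3.31) and Prl2c3, and downward Cdkn1c (-5.36, adjusted p = 0.0157), Parm1, Asb2, Col8a2 and the nicotinamide riboside kinase gene Nmrk2. Prl2c3 was not above background in DMSO cells at 48 h, and the last 4 were not above background in DMSO cells in growth medium, so the size and rank of these differences are uncertain. Ep300 (0.67, adjusted p = 0.0221), Myod1 (-0.95, adjusted p = 0.0151), Mef2c (-1.51, adjusted p = 0.00474) and Hmox1 (1.60, adjusted p = 0.00141) were among the genes called, and Kat2b, Kat2a, Crebbp, Myog and Cdkn1a were not. Without replicate 1 of embelin in growth medium, which leaves the array that stood apart, Myog was called at -1.99 (adjusted p = 0.000195). Without replicate 2 of embelin at 48 h the calls of Saa3 (adjusted p = 0.11), Angptl4 (0.0524), Cdkn1c (0.0633), Ep300 (0.0917) and Myod1 (0.0634) were lost, and 1751 genes were called. The difference was called in 20 of 21 G2/M genes, 20 of 31 sarcomere genes and 13 of 15 interferon genes, all downward, and in 16 of 23 glycolysis and hypoxia genes and 5 of 5 aryl hydrocarbon receptor targets, all upward. Adjusted over the list alone these counts were 21, 26, 14, 21 and 5. The difference was called, without replicate 2 of embelin at 48 h, in 11 sarcomere and 9 glycolysis and hypoxia genes, without replicate 2 of DMSO in growth medium in 11 and 10, and without replicate 2 of DMSO at 48 h in 13 and 10. At 24 h no gene passed limma for this difference, with 811 at an unadjusted p under 0.05. Kat2b, Kat2a, Ep300, Crebbp, Myod1, Myog, Mef2c, Cdkn1a and Hmox1 were not called there (adjusted p from 0.722 to 0.995). The count at 24 h was 256 without replicate 1 of embelin in growth medium, and without replicate 2 it was 1, Prss23 at 1.68 (adjusted p = 0.0478).

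The mean embelin effect over the 3 stages set 6 arrays against 6 and called 2842 genes, 1451 higher and 1391 lower (1437 and 740 under median scaling), of which 67 moved by at least 1 log2 unit. Among genes with the same sign at every stage, the 10 increases named by the fixed rule were Cp (1.46), Aldh3a1 (1.34), Ndrg1 (1.30), Slc2a3 (1.27), Tmem45a (1.16), the hypoxia-inducible carbonic anhydrase gene Car9, Mmp13, AK3L1, Kbtbd11 and Vwa1. The 10 decreases were H2ac12 (-1.49, SE 0.15), H2ac22 (-1.47), H2ac15 (-1.47), H2ac11 (-1.45), Birc5 (-1.20), H2ac21 (-1.19), the maintenance methylation gene Uhrf1 (-1.08), Tceal6, Fsd2 and Troap. The last 5 increases and the last 3 decreases were not above background in at least 1 group, so their size and rank are uncertain. The highest adjusted p among these 20 was 0.00301. Kat2b was higher by 0.36 (adjusted p = 0.00806) and Hmox1 by 0.54 (adjusted p = 0.00387), while Cdkn1a (0.25, adjusted p = 0.0203) and Mef2c (-0.41, adjusted p = 0.0308) lost their calls without replicate 1 of DMSO in growth medium (adjusted p = 0.0607 and 0.0538), among other single arrays. Kat2a (-0.14, adjusted p = 0.173), Ep300 (0.18, adjusted p = 0.094), Crebbp (0.05, adjusted p = 0.956), Myod1 (-0.08, adjusted p = 0.605) and Myog (0.28, adjusted p = 0.494) did not pass, though without replicate 1 of embelin in growth medium Kat2a (-0.21, adjusted p = 0.02) and Myog (0.62, adjusted p = 0.000902) did. The same fit called 6 genes at 24 h and 0 in growth medium, so this mean rests mostly on the 48 h arrays. Without replicate 2 of embelin in growth medium the count was 2934.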

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

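Of the tests in this part, the one on H2A probe correlation was set before its result was seen, and those on the array that stood apart, on slower differentiation and on S phase were chosen after. What marked a result here was a tested difference between the embelin effect at 48 h in differentiation medium and the embelin effect in growth medium, and 2736 genes had such a difference at an adjusted p under 0.05. Among genes named in this text, the muscle genes and regulators of cell cycle exit with a negative difference (log2) were Cdkn1c -5.36, Asb2 -4.15, Nmrk2 -3.78, Ckm -3.57, Actn2 -3.37, Pgam2 -3.14, Cox8b -3.04, Ckmt2 -2.99, Dhrs7c -2.85, Ampd1 -2.74, Fsd2 -2.68, Myh8 -2.62, Hrc -2.47, Myh1 -2.36, Mybpc1 -2.21, Adam12 -1.92, Atp2a1 -1.85, Myf6 -1.63, Mef2c -1.51, Dysf -1.20, Tead4 -1.02, Hspb2 -1.002, Myod1 -0.95 and Smyd1 -0.94. Part of these differences comes from replicate 2 of embelin in growth medium, without which the sarcomere median of -1.56 became -0.91. Cell cycle genes with a negative difference were Mki67 -3.12, Birc5 -2.99, Aurkb -2.89, Plk1 -2.81, Mcm5 -2.74, Uhrf1 -2.59, Tk1 -2.59, Troap -2.48, Mcm10 -2.26, Chaf1b -1.83 and Foxm1 -0.97. Interferon response genes were Oasl2 -3.13, Ifit3 -3.07, Usp18 -2.99 and Igtp -2.29. Further negative differences were those of Parm1 -5.30, Col8a2 -3.96, Igfbp3 -3.56, Lama1 -3.33, Heyl -3.05, Tceal6 -3.03, Tceal5 -2.84, Hey1 -2.42, Pmaip1 -2.22, Ppargc1a -1.88, Mvd -1.79, Hdac11 -1.77, Idh3a -1.41, Gpt2 -1.25, Bid -1.25, Dhcr7 -1.25, Cycs -1.15, Phgdh -0.92, Sirt2 -0.71 and Hspb1 -0.63.

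Positive differences among inflammatory, secreted and matrix genes were those of Saa3 4.28, Prl2c3 3.62, Cxcl12 3.31, Ptx3 3.25, Nos2 3.23, Cxcl1 3.13, Cp 2.85, Mmp13 2.83, Mmp3 2.82, Tnfsf9 2.26, Osmr 2.24, Socs3 2.15, Il6ra 1.98, Il33 1.97, Nfkbiz 1.81, Ccn1 1.68, Fn1 1.61 and Lox 1.43. Genes of hypoxia, glucose use and stress followed with Angptl4 3.995, Car9 2.67, Ndrg1 2.62, Egln1 2.19, Slc2a3 2.14, Tmem45a 1.74, Slc2a1 1.61, AK3L1 1.29, Ddit3 1.09 and Vldlr 1.06. Other genes with a positive difference were Car12 3.46, Aldh3a1 3.27, Rasl11a 3.23, Mt2 2.86, Kbtbd11 2.74, Vwa1 2.58, Ugt1a6a 2.33, Grem1 2.14, Mt1 2.11, Id2 1.92, Epha2 1.69, Cyp1b1 1.69, Igfbp2 1.66, Hmox1 1.60, Gstm1 1.40, Mdm2 1.35, Trp53inp1 1.34, Bcl2l1 1.29, Ccng1 1.25, Twist2 1.09, Irs2 1.08, Cxcr4 0.95, Foxo3 0.87, Hsp90b1 0.67, Ep300 0.67, Kat6b 0.60 and Kat5 0.58. Histone genes differed both ways, with H2ac23 -3.33, H2ac12 -3.19, H2ac15 -3.14, H2ac22 -2.93, H2ac11 -2.89, H2ac21 -2.05, H2ac20 -1.65, H2ac13 -1.50, H2ac10 -1.06, H2bc11 0.77, H2ac19 1.39 and H2ac18 1.71. Among these genes, 12 lost their call in some of the 12 fits that leave out an array: Atp2a1 in 10 (highest adjusted p = 0.109), Saa3 in 10 (highest adjusted p = 0.11), Smyd1 in 7 (highest adjusted p = 0.128), Kat5 in 7 (highest adjusted p = 0.104), H2bc11 in 5 (highest adjusted p = 0.0891), Ep300 in 4 (highest adjusted p = 0.0917), Sirt2 in 3 (highest adjusted p = 0.0746), Kat6b in 3 (highest adjusted p = 0.0653), Cdkn1c in 2 (highest adjusted p = 0.0633), Myod1 in 2 (highest adjusted p = 0.0634), Hspb1 in 2 (highest adjusted p = 0.0647) and Angptl4 in 1 (highest adjusted p = 0.0524).

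Of these 126 genes, 37 were detected on no array of at least 1 of the 4 groups compared, so their values are in part differences against background and are read for direction only. They are Parm1, Asb2, Col8a2, Nmrk2, Ckm, Igfbp3, Actn2, Oasl2, Ifit3, Heyl, Tceal6, Ckmt2, Usp18, Dhrs7c, Tceal5, Ampd1, Fsd2, Myh8, Troap, Myh1, Igtp, Mcm10, Pmaip1, Mybpc1, Ppargc1a, Hdac11, Myf6, Smyd1, AK3L1, Il33, Vwa1, Car9, Kbtbd11, Mmp3, Mmp13, Nos2 and Prl2c3.

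Replicate 2 of embelin in growth medium stood apart from its group, with genes of differentiated muscle raised. On an axis from growth medium (0) to 24 h in differentiation medium (1) it lay at 0.305, away from every other array, which excludes a simple exchange of labels. If RNA of differentiated cells were mixed in, 417 genes that rise in differentiation give a share of 13.6% (quartiles 10.7 and 16.6). The 113 genes that fall in differentiation then lay 0.11 lower than that share predicts (difference -0.11), which neither excludes nor requires such a mixture. Cells that had begun to differentiate in growth medium would give the same pattern, and this was not tested apart from it.

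Muscle genes and cell cycle genes were both lower with embelin at 48 h. Over 58 genes of the 2 muscle lists, embelin cells at 48 h lay 0.35 above DMSO cells at 24 h and 0.79 below DMSO cells at 48 h (median -0.79), in line with slower differentiation. G2/M genes do not follow that account: they fall between 24 h and 48 h in DMSO cells (median -0.73), and in embelin cells at 48 h they lay below DMSO cells at 48 h (median -2.44). Interferon genes, which rise between 24 h and 48 h in DMSO cells (median 0.72), lay below the DMSO cells of 24 h (median -0.50, 8 lower and 0 higher). Slower differentiation alone is therefore excluded for the cell cycle genes and does not account for the interferon genes, and it stays open for the muscle genes.

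H2A genes were the only genes called lower with embelin at 24 h, where 4 of 13 were lower and 11 were negative. Their deviations within groups had a median correlation of 0.503, against a 95th percentile of 0.134 over 1000 random sets. Probes of near-identical genes sharing a signal would give this, and so would genes that vary together. The random sets were matched only in size and signal level, so the test cannot tell these apart. Either way the 4 calls, with H2ac20 read in opposite directions by its probes at 48 h, may be fewer independent results. Fewer cells in S phase would lower the replication genes too, and their median at 24 h was -0.27. Camera with an estimated correlation did not call the list (adjusted p = 0.321), but it called 0 of the 27 lists in every comparison, so it cannot decide this. Other histone genes do not settle it. In DMSO cells at 48 h, where the replication median was -2.21, H2A genes fell in 11 and rose in 2 of 13. H2B genes rose there in 8 of 9 and fell in 0, and their median with embelin at 24 h was 0.04. The S-phase account remains open.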

How the results depend on the processing

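Of the alternatives, 3 were chosen after seeing the data: other baselines for the slope, and the estimated correlation without replicate 2 of embelin in growth medium. Over all alternatives, the named genes stayed on their side of the threshold in 14712 of the values recomputed, lost the call in 346 and gained it in 39. Direction was compared only for values called in the main analysis, and it reversed in 0 for genes. With every probe, a named gene kept its main probe, so it could not reverse there. Nor can a fold change move when the array left out lies outside the compared groups. Gene lists stayed on their side in 2812, lost the call in 276, gained it in 39 and, where called in the main analysis, reversed in 5. Counts of genes stayed within 1.5 times the main count in 233 cases and moved in 36. The mean of the 2 slopes counted as moved only where it changed by at least their standard deviation, and it moved in 0 of 12. That tolerance is wide. The slope for number 2 was 0.639, but 0.825 with the mean of the DMSO growth-medium arrays as the baseline, and this still counted as unmoved.

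The count for embelin at 24 h, 6 in the main analysis, changed under many of the alternatives. It was 51 without background correction, 42 with normexp and an offset of 50, 27 with a neqc offset of 50, 12 with the series matrix, 3 without a detection filter and 10 over every probe. It was 0 under median scaling and 0 under 75th percentile scaling, 0 with the replicate block, 39 with a trended and robust prior, 12 with array weights and 0 with the compared arrays only. Leaving out each array gave 0 to 9. The interaction at 24 h, 0 in the main analysis, became 4 with a trended and robust prior and 0 to 256 with an array left out. Embelin in growth medium, 0 in the main analysis, gave 0 to 338 with an array left out, the highest without replicate 1 of embelin in growth medium. At 48 h the count for embelin ran from 2939 to 4951 with an array left out, and the interaction from 1751 to 2732, the lowest in both cases without replicate 2 of embelin at 48 h. Leaving out an array moved counts both up and down. An array outside the compared groups can act only through the pooled spread. This holds for the highest count for embelin at 48 h, which came without either embelin array in growth medium. For arrays of the compared groups the cause was not tested.

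Stricter thresholds lower the counts by construction. At an adjusted p under 0.01 there were 2910 genes for embelin at 48 h, 1386 for the interaction at 48 h, 1393 for the mean embelin effect and 0 for embelin at 24 h. With a log2 fold change of at least 1 as well as an adjusted p under 0.05 there were 0 for embelin at 24 h, 1005 at 48 h, 2007 and 2548 for DMSO cells at 24 h and 48 h, 1961 and 2464 for embelin cells, 1068 for the interaction at 48 h and 67 for the mean effect. By the labels, samples share only a replicate number. Correlations of deviations between groups ran from -0.03 to 0.24 over 15 pairs of groups, with 7 above 0.1, all of them among the 10 pairs without embelin in growth medium, a hint of a shared effect of the number in the other groups. With the replicate block no count other than that at 24 h moved by over 1.5 times, with 4665 genes for embelin at 48 h and 7230 for DMSO cells at 48 h.

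The mitochondrial list at 48 h in DMSO cells reversed under median scaling, from 0.18 to -0.11, a setting that moved the median of all genes to -0.33. In growth medium, the embelin medians of the glycolysis and hypoxia list and of the insulin-like growth factor list were -0.0481 and -0.0483 without replicate 2 of embelin, with the preset and with the estimated correlation, and 0.20 and 0.28 without replicate 1. Every one of the 27 fixed lists called by camera with the preset correlation lost its call with an estimated correlation. That test called 0 lists in every comparison, its lowest adjusted p being 0.115, for the mean embelin effect. Among those lost were the sarcomere genes of DMSO cells at 48 h, with a median rise of 4.81 log2 units. Failing it therefore does not part lists that moved from lists that did not. The fry test, which takes a list by itself rather than against the other genes, called 22 lists for embelin at 48 h. It called 25 for DMSO cells at 48 h and 20 for the interaction at 48 h, where camera with the preset correlation called 15 each. For embelin at 24 h fry called 2 lists against 13 by camera, and in growth medium 0 against 12. The slide block was not run, since no slide is named. Signal over background limits genes near the detection threshold. Between a pair of groups their change is given as a bound, and over several groups only its direction is read.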

Other observations

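The genes and gene families in the opening paragraphs were chosen after their values were seen, as was every test here except those on the added hypoxia list and on splits of the arrays. Histone genes were counted by family with embelin at 48 h, without a set test, and near-identical members may share a signal. Of 13 measured H2A genes of the H2ac family, 10 were lower and 2 higher (median log2 fold change -2.34; -2.27 to -1.62 under the other normalizations). The 2 that were higher were H2ac18 (adjusted p = 8.42e-05) and H2ac19 at 1.59 (SE 0.16, adjusted p = 3.68e-05). Of 9 H2B genes of the H2bc family, 8 were higher and 0 lower (median 0.87; 0.76 to 0.98 under the other normalizations), with H2bc11 at 0.96 (adjusted p = 0.000635) and H2bc4 at 0.87 (adjusted p = 0.00208). The same 9 genes had 8 higher and 0 lower in DMSO cells between growth medium and 48 h, with a median of 1.82, H2bc11 rising by 2.10 and H2bc4 by 2.27. H3 genes had 1 higher and 3 lower of 7 (median -0.29) and H4 genes 3 higher and 0 lower of 8 (median 0.47). At 24 h none of the H2B genes was called, and their median was 0.04.

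Several single genes, for which no list was tested, were also far higher with embelin at 48 h. The feedback inhibitor gene Socs3 was higher by 2.36 (SE 0.19, adjusted p = 9.61e-06), the receptor genes Osmr by 2.32 (SE 0.21, adjusted p = 1.73e-05) and Il6ra by 2.00 (SE 0.13, adjusted p = 3.19e-06), and the cytokine gene Il33 by 2.45 (SE 0.27, adjusted p = 5.67e-05). The pentraxin gene Ptx3 was higher by 3.16 (SE 0.26, adjusted p = 9.61e-06), the nitric oxide synthase gene Nos2 at least 6.53-fold (adjusted p = 2.03e-06), and the stromelysin gene Mmp3, detected on 1 of the 2 DMSO arrays, by 2.85 (SE 0.26, adjusted p = 2.11e-05). The metallothionein genes Mt1 and Mt2 were higher by 2.12 (SE 0.25, adjusted p = 0.00011) and 2.54 (SE 0.21, adjusted p = 1e-05). Both fell during differentiation of DMSO cells, with log2 fold changes of -1.68 (adjusted p = 0.000189) and -2.07 (adjusted p = 8.97e-06) at 48 h.

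A hypoxia-type response at 24 h was tested on another list of 17 measured hypoxia-inducible genes, none of them in the fixed list. Their median log2 fold change with embelin at 24 h was 0.47, and all 17 were positive though none was called alone (camera p = 1.82e-12, and p = 0.00812 with an estimated correlation). At 48 h 15 were higher and 1 lower, with a median of 1.13 (camera p = 1.89e-08, and p = 0.0212 with an estimated correlation). In growth medium the median was 0.13 (camera p = 0.0121, and p = 0.216 with an estimated correlation). That comparison includes replicate 2 of embelin, the array that stood apart. Without it, the growth-medium median of the fixed glycolysis and hypoxia list went from 0.097 to -0.048. The p-values of the added list were not adjusted over lists, whereas those of the fixed lists were. They therefore cannot be set against the fixed glycolysis and hypoxia list at 24 h (camera adjusted p = 0.143 with an estimated correlation). Both lists were read on the same arrays, so the added list is not independent evidence. Its shift at 24 h is compatible with a hypoxia-type response to embelin under way by then, and oxygen or HIF protein was not measured.

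For the mean embelin effect, the 12 arrays were split in 100 of the 108 ways that put 2 arrays of each stage on each side. As many genes as the 2842 of the real split came from 3 of the 100, the real one included, and the highest other count was 2900. In 33 of the 100 splits both embelin arrays of 48 h stay on the same side, and among the rest the highest count was 8. The mean therefore separates the treatments at 48 h and adds little about the other stages.

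The values of Crebbp split by replicate number rather than by group: number 2 lay above number 1 by 1.54 log2 units (adjusted p = 0.000423), and 13 genes in all differed between the numbers. The cause was not tested.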
